A study of Mus musculus with 19 samples.

How the data were processed

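Bulk RNA sequencing was done on 19 liver libraries of male C57BL/6J mice. According to the labels, total RNA was extracted with a PureLink kit and the libraries were stranded mRNA libraries (TruSeq). Per the submitters' processing notes, reads were quantified with Salmon 1.10.1 on genome build GRCm39. DESeq2 1.38.3 is also named there with no role given, and neither the transcript set nor the index options are stated. The deposited files hold 1 quantification per library with 3 kinds of value: estimated counts per transcript (expected counts, not scaled between libraries), TPM (transcript abundance scaled by effective length within the library), and as another unit the effective length of each transcript in bases, estimated per library. All deposited estimated counts were used. The deposited effective lengths entered 1 alternative, averaged per gene with the TPM values as weights, and the TPM values entered no other test.

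Each file listed the same 116546 transcripts. Of these, 115977 (99.51%) were found by identifier in the GENCODE M21 annotation, which belongs to the earlier build GRCm38, and 115785 of them had the same version. Gene symbols and biotypes come from GENCODE M21, some may have been renamed since, and no coordinates are given. The remaining 569 transcripts were left out, with 0.0623% to 0.1095% of the reads of a library. Counts were summed to 35498 genes, of which 21794 are protein-coding, and rounded to whole numbers.

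The groups were taken from the labels, and replicates are numbered in the order of deposition. No animal is named as shared between libraries, so no paired test was made. Depth ran from 17253823 to 23450232 estimated reads per library, and between 11756 and 13609 genes had at least 10 counts. Counting error follows from this depth alone. Reads without molecular identifiers are not independent molecules, so a floor of 3 counts covers counting error only.

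The tests were run in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr on the 4 groups, which left 13594, and libraries were scaled by TMM (trimmed mean of M values). A model with a mean per group was fitted to all 19 libraries with robust dispersion estimates (common dispersion 0.0341) and the quasi-likelihood F test. The 5 contrasts were WSD against CTRL, WSD+beta-Glucan against WSD, CTRL+beta-Glucan against CTRL, WSD+beta-Glucan against CTRL+beta-Glucan, and the difference between both beta-glucan effects. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values (counts scaled to a common library size) are means with the SD over libraries, and log2 CPM used a prior count of 2.

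Gene lists for liver cell types, pathways and possible admixed tissues were written down from textbook knowledge, 42 in number, of which 40 had at least 3 tested members; those of exocrine pancreas and of skeletal and cardiac muscle did not and were not tested. Each was tested with camera (limma 3.58.1), which compares its members with all other genes, once with a preset correlation of 0.01 and once with an estimated correlation. The p-values were adjusted over the lists within the contrast. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. A list's score in a library is the mean log2 CPM of its tested members, and scores were compared between groups by two-sided exact permutation tests.

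Genes are named by fixed criteria. In each contrast these take the 6 highest and the 6 lowest log2 fold changes among protein-coding genes that passed the threshold and had an assigned symbol (not Gm with digits, not ending in Rik). A mean of at least 2 CPM over the groups compared and no overlap between the libraries of both groups were also asked for, the latter not for the difference between the effects. From each list with a camera adjusted p under 0.05, they take the 3 members past the threshold with the smallest p, from which the text quotes a selection. A set of 24 genes of liver injury, lipid metabolism and microbial sensing was also tested in every contrast, and the text quotes a selection of them. The groups, contrasts, tests, gene lists, naming criteria and most alternatives were fixed before the data were examined. Genes named outside these criteria are said to have been chosen after their values were seen.

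The agreement between both WSD effects was measured across genes by Pearson's r, whose SE comes from leaving out libraries in turn, and by the overlap of calls against the overlap of independent lists. The opposing effect of beta-glucan was measured with the WSD libraries split between both contrasts, and compared with counts simulated from the fitted means and dispersions. The edgeR test, DESeq2 1.42.0 and limma-voom were tested on simulated data with known changes in 1.5, 2 or 4-fold steps. The changed genes had a mean of at least 2 CPM over all libraries. At 1.5-fold only the raised genes were scored, at 2 and 4-fold those of both directions. A gene counted as recovered when it passed the threshold.

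The alternatives were DESeq2 size factors (RLE), no filter on low counts, a filter at 1 CPM in at least 4 libraries, DESeq2, limma-voom with sample quality weights, offsets from average transcript lengths, a fit to only the groups compared, leaving out the 3 libraries numbered 37, 39 and 40, a model term for them, TMM without the 50 most abundant genes, and leaving out each library in turn. The same alternatives for the gene lists were, apart from the estimated correlation, the adjustment over the list alone and the camera test without the 3 libraries, chosen after seeing the data.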

Results

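RNA was sequenced from livers of male C57BL/6J mice that the labels place at 24 weeks and in 4 treatment groups. These were CTRL (n = 5 libraries), CTRL+beta-Glucan (n = 5), WSD (n = 5) and WSD+beta-Glucan (n = 4). According to the series title, the study concerns oat beta-glucan in the diet, a soluble cereal fibre, the gut microbiota and the progression of fatty liver disease. The labels do not spell out WSD, and it is used here as a group name only. Nothing in the labels says that each library came from a different mouse, so the p-values measure the spread between these samples, which may be technical. No 2 libraries held the same counts, and each was used as 1 replicate.

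Between 17253823 and 23450232 estimated reads were assigned per library, with a median of 19481377. Mean depth was 20056646 ± 1993812 reads (SD) in CTRL, 19951439 ± 2584588 in CTRL+beta-Glucan, 19096025 ± 1018031 in WSD and 20458332 ± 2589752 in WSD+beta-Glucan. The 50 most abundant genes took 40.3 ± 1.26% of the counts in CTRL and 40.7 ± 1.91% in CTRL+beta-Glucan, against 32.5 ± 1.08% in WSD and 34.9 ± 1.36% in WSD+beta-Glucan. At least 10 counts were found for 12240 ± 98.7 genes in CTRL and for 13340 ± 162 genes in WSD. On the first principal component of log2 CPM (counts scaled to library size), which held 58.3% of the variance, CTRL lay at -48.9 ± 9.8, CTRL+beta-Glucan at -45.1 ± 11, WSD at 63.8 ± 9.8 and WSD+beta-Glucan at 37.6 ± 11 (mean ± SD). The difference between WSD+beta-Glucan and WSD on this component had an exact permutation p = 0.0159 (two-sided), the smallest that 4 against 5 libraries allow. For CTRL+beta-Glucan against CTRL the exact permutation p was 0.563. Along the second component, with 6.68% of the variance, the 3 libraries whose titles start with 37, 39 and 40 stood apart within their groups: WSD+beta-Glucan replicate 1 and CTRL+beta-Glucan replicates 1 and 2. These titles carry low S numbers, and S2 also occurs in another title, so they may come from another sequencing sheet.

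**Figure D1:**
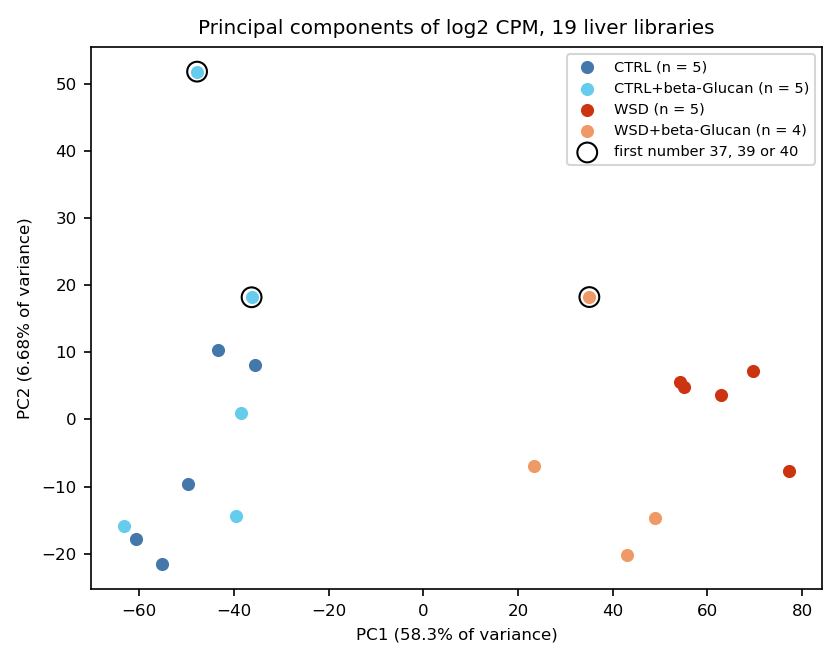
First principal component (x axis, 58.3% of variance) against second (y axis, 6.68%) of log2 CPM, with 1 point per liver library coloured by group. The WSD+beta-Glucan libraries lie between the CTRL and WSD libraries on the x axis, and the 3 ringed libraries, with 37, 39 or 40 as first number in the title, lie highest within their groups on the y axis.

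What WSD did to the liver without beta-glucan was the question of the comparison of WSD with CTRL. Most monocyte and macrophage markers and genes of MHC class II presentation rose. Most fibrosis and extracellular matrix genes also rose and most cholesterol biosynthesis genes fell, but the calls of these 2 lists were lost, with adjusted p = 0.151 and adjusted p = 0.0551 with an estimated correlation. Gpnmb (ENSMUSG00000029816), a membrane glycoprotein of lipid-laden macrophages, was at 88.6 ± 14.8 CPM in WSD (SD, n = 5) and 0.159 ± 0.201 CPM in CTRL (SD, n = 5), a log2 fold change of 9.06 ± 0.53 (SE) whose size is uncertain, with 14 reads over all CTRL libraries. Trem2 (ENSMUSG00000023992), a lipid receptor of the same cells, was at 25.7 ± 4.9 and 0.425 ± 0.167 CPM, a log2 fold change of 5.91 ± 0.37. Col1a1 (ENSMUSG00000001506), a chain of type I collagen, was at 108 ± 43.8 and 3.83 ± 2.05 CPM, a log2 fold change of 4.82 ± 0.46. Of 13594 genes tested with edgeR, 3528 were higher and 3680 lower at an adjusted p under 0.05, and 2152 of the higher but only 408 of the lower changed by at least 2-fold. Which direction had more calls depended on the setting: 3708 were higher and 3303 lower with RLE, 3734 and 3316 without the filter, 3763 and 3392 with DESeq2, 3591 and 3219 with edgeR on these 10 libraries alone, and 3603 and 3596 without WSD+beta-Glucan replicate 1.

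Among the 6 highest log2 fold changes that the naming criteria admitted were also Ephb2, an ephrin receptor (6.40 ± 0.45, adjusted p = 4.51e-09), and Mmp12, the macrophage elastase (5.99 ± 0.23, adjusted p = 8.41e-13). The remaining members of this group, Timp1, an inhibitor of matrix-degrading enzymes, Sprr1a and Lrtm2, had 5, 1 and 2 reads over the 5 CTRL libraries and 6.37 ± 2.29, 8.62 ± 3.4 and 6.37 ± 2.02 CPM in WSD, so no fold is given for them. The reads of Timp1 were all in CTRL replicate 1. The 6 lowest log2 fold changes were those of Mup7 (-6.54 ± 1.51), Mup15 (-5.65 ± 1.15), Mup12 (-5.64 ± 1.13), Mup9 (-5.16 ± 1.21) and Mup2 (-5.01 ± 0.86), which encode major urinary proteins, and of Serpina1e (-4.94 ± 0.62), an alpha-1 antitrypsin gene. Both families have near-identical copies, and the split of reads between their members is uncertain.

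Several lists of immune genes rose as groups. All 24 monocyte and macrophage markers passed as higher (24 adjusted over the list alone), with a median log2 fold change of 3.16. Ccr2, the chemokine receptor of recruited monocytes, changed by 3.89 ± 0.24, and Mpeg1, a pore-forming protein of phagocytes, by 3.38 ± 0.20. Of 19 lipid-associated macrophage genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 3.26. They included Lpl, the lipoprotein lipase (4.01 ± 0.17), and Capg, an actin-capping protein (3.96 ± 0.20). All 10 genes of antigen presentation by MHC class II rose (10 adjusted over the list alone, median 3.60), with H2-Aa at 3.91 ± 0.28 and Ciita, their transcriptional coactivator, at 3.51 ± 0.27. Among 29 inflammatory cytokines and chemokines, 24 rose and 1 fell (25 and 1 adjusted over the list alone, median 2.70), with Ccl2, a monocyte attractant, at 4.80 ± 0.34 and Tnf at 3.15 ± 0.35. Microbial sensing genes showed 26 higher and 5 lower of 35 (26 and 5 adjusted over the list alone, median 1.74). In that list Clec7a, which encodes the beta-glucan receptor dectin-1, changed by 4.49 ± 0.29, and Cd14, a co-receptor for bacterial lipopolysaccharide, by 2.72 ± 0.32. Interferon-stimulated genes rose in 35 of 38 cases and fell in 0 (35 and 0 adjusted over the list alone, median 1.4), with Oas1a at 3.18 ± 0.15. These 6 lists passed camera with a preset correlation (adjusted p from 4.1e-09 to 1.5e-26), and also with an estimated correlation (adjusted p = 0.0234, 0.00316, 0.0234, 0.00717, 0.00884 and 0.0170 in the order given).

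Markers of several other cell types were also higher. T and NK cell markers rose in 20 of 22 cases (20 adjusted over the list alone, median 1.79), but the camera call was lost, with adjusted p = 0.239 with an estimated correlation. Dendritic cell markers rose in 10 of 11 cases (10 adjusted over the list alone, median 1.80, adjusted p = 0.0492 with an estimated correlation). Endothelial markers rose in 17 of 24 cases (17 adjusted over the list alone, median 0.76) and hepatic stellate cell markers in 13 of 18 (13 adjusted over the list alone, median 1.20). Their camera calls were lost, with adjusted p = 0.550 and adjusted p = 0.387 with an estimated correlation. Cholangiocyte markers rose in 7 of 17 cases (7 adjusted over the list alone, median 1.31, adjusted p = 0.597 with an estimated correlation), and the keratin gene Krt8 changed by 1.63 ± 0.14. Krt8 had 18523 reads over the CTRL libraries, while the list's mean score there was 1.36. Its change cannot be assigned to cholangiocytes. Resident Kupffer cell markers had 7 members higher and 2 lower of 14 (7 and 2 adjusted over the list alone, median 0.87) and did not pass camera (adjusted p = 0.0536). Clec4f, one of them, changed by 1.53 ± 0.38, while Timd4, another, did not pass, at -0.35 ± 0.46 (adjusted p = 0.542). Neutrophil markers had 1 of 9 higher and B and plasma cell markers 4 of 12 (1 and 4 adjusted over the list alone), with camera adjusted p of 0.400 and 0.165. The mean scores per library of these 3 lists were higher, by 0.70, 0.73 and 0.63 (exact permutation, adjusted p = 0.0227, 0.0227 and 0.0423).

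Fibrosis and extracellular matrix genes rose in 36 of 42 cases and fell in 1 (36 and 1 adjusted over the list alone), with a median log2 fold change of 2.14. Camera gave adjusted p = 2.5e-16 with the preset correlation and adjusted p = 0.151 with an estimated correlation. Besides Col1a1 and Timp1, Col4a1, a basement membrane collagen, changed by 2.13 ± 0.18. Spp1, osteopontin, which is not in this list but among the lipid-associated macrophage genes, changed by 2.70 ± 0.51. Acta2, the smooth muscle actin of activated stellate cells, did not pass (-1.25 ± 1.1, adjusted p = 0.358), and its CPM spread widely in CTRL (9.87 ± 16.9) and less in WSD (4.12 ± 1.36). Cell cycle genes rose in 29 of 33 cases and fell in 0 (30 and 0 adjusted over the list alone, median 2.47, adjusted p = 0.0193 with an estimated correlation). Mki67, a marker of dividing cells, changed by 3.59 ± 0.27, from 0.590 ± 0.347 CPM in CTRL to 7.11 ± 1.4 in WSD. Genes of senescence, death and damage rose in 15 of 20 cases and fell in 0 (15 and 0 adjusted over the list alone, median 1.32, adjusted p = 0.0492 with an estimated correlation), with Gdf15, a stress-induced hormone, at 3.43 ± 0.27. Immediate early genes rose in 11 of 18 cases (11 adjusted over the list alone, median 0.97), and the call was lost, with adjusted p = 0.184 with an estimated correlation. Targets of NRF2 in the oxidative stress response rose in 15 and fell in 3 of 28 cases (15 and 3 adjusted over the list alone, median 0.42, adjusted p = 0.279 with an estimated correlation).

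Lipid lists moved in both directions. Cholesterol biosynthesis genes fell in 22 of 27 cases and rose in 0 (22 and 0 adjusted over the list alone, median -1.11, camera adjusted p = 8.1e-16, adjusted p = 0.0551 with an estimated correlation). Tm7sf2, a sterol reductase, went from 113 ± 11.9 CPM in CTRL to 22.1 ± 2.87 in WSD (-2.36 ± 0.12), and Idi1, an isomerase of the pathway, changed by -2.88 ± 0.22. Fatty acid oxidation genes and PPAR alpha targets fell in 32 of 42 cases and rose in 1 (32 and 1 adjusted over the list alone, median -0.70, adjusted p = 0.307 with an estimated correlation), with Cpt1a, the carnitine transferase of mitochondrial import, at -0.87 ± 0.18. De novo lipogenesis was divided, with 10 members higher and 10 lower of 25 (10 and 11 adjusted over the list alone). Its median was -0.26, its mean 0.41 and its camera direction up (adjusted p = 0.192), and its mean score per library was higher by 0.43 (exact permutation, adjusted p = 0.0127). Scd1, a desaturase, changed by 1.83 ± 0.22, Srebf1, the transcription factor of the pathway, by 1.71 ± 0.18 and Fasn, the fatty acid synthase, by 0.97 ± 0.18. Of the lipid droplet genes 12 rose and 9 fell of 28 (12 and 9 adjusted over the list alone, camera adjusted p = 0.572), and their mean score was higher by 0.49 (exact permutation, adjusted p = 0.0127). Cidec, a droplet protein, passed at 1.48 ± 0.58 (adjusted p = 0.0438) but lost its call in 14 of the 29 other settings (adjusted p up to 0.0956), and Plin2, the droplet coat protein, did not (-0.16 ± 0.13, adjusted p = 0.307). Fgf21, a hepatic hormone, also did not pass, at 0.86 ± 0.45 (adjusted p = 0.114), but passed at 1.39 without CTRL replicate 3 (adjusted p = 0.00996).

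Glucose metabolism genes fell in 17 and rose in 4 of 25 cases (18 and 4 adjusted over the list alone, median -0.56, adjusted p = 0.0551 with an estimated correlation). The gluconeogenic genes G6pc and Pck1 changed by -1.88 ± 0.20 and -2.29 ± 0.26. Bile acid genes fell in 16 and rose in 4 of 32 cases (16 and 4 adjusted over the list alone, median -0.23, adjusted p = 0.441 with an estimated correlation). Slc10a1, the bile acid importer of hepatocytes, changed by -1.25 ± 0.13, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (-0.06 ± 0.75, adjusted p = 0.956). General hepatocyte markers fell in 14 of 20 cases (15 adjusted over the list alone, median -0.62, adjusted p = 0.266 with an estimated correlation), and periportal genes fell in 12 and rose in 2 of 18 (12 and 2 adjusted over the list alone, median -0.83, adjusted p = 0.252 with an estimated correlation). Male-biased liver genes fell in 22 of 26 cases and rose in 0 (23 and 0 adjusted over the list alone, median -1.94, camera adjusted p = 9.4e-10). This call was lost, with adjusted p = 0.226 with an estimated correlation. Elovl3, a fatty acid elongase, changed by -2.76 ± 0.27 and C8b, a complement component, by -2.23 ± 0.23. Transcripts of the mitochondrial genome fell in 8 of 13 cases (9 adjusted over the list alone, median -0.62, adjusted p = 0.550 with an estimated correlation).

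**Figure D2:**
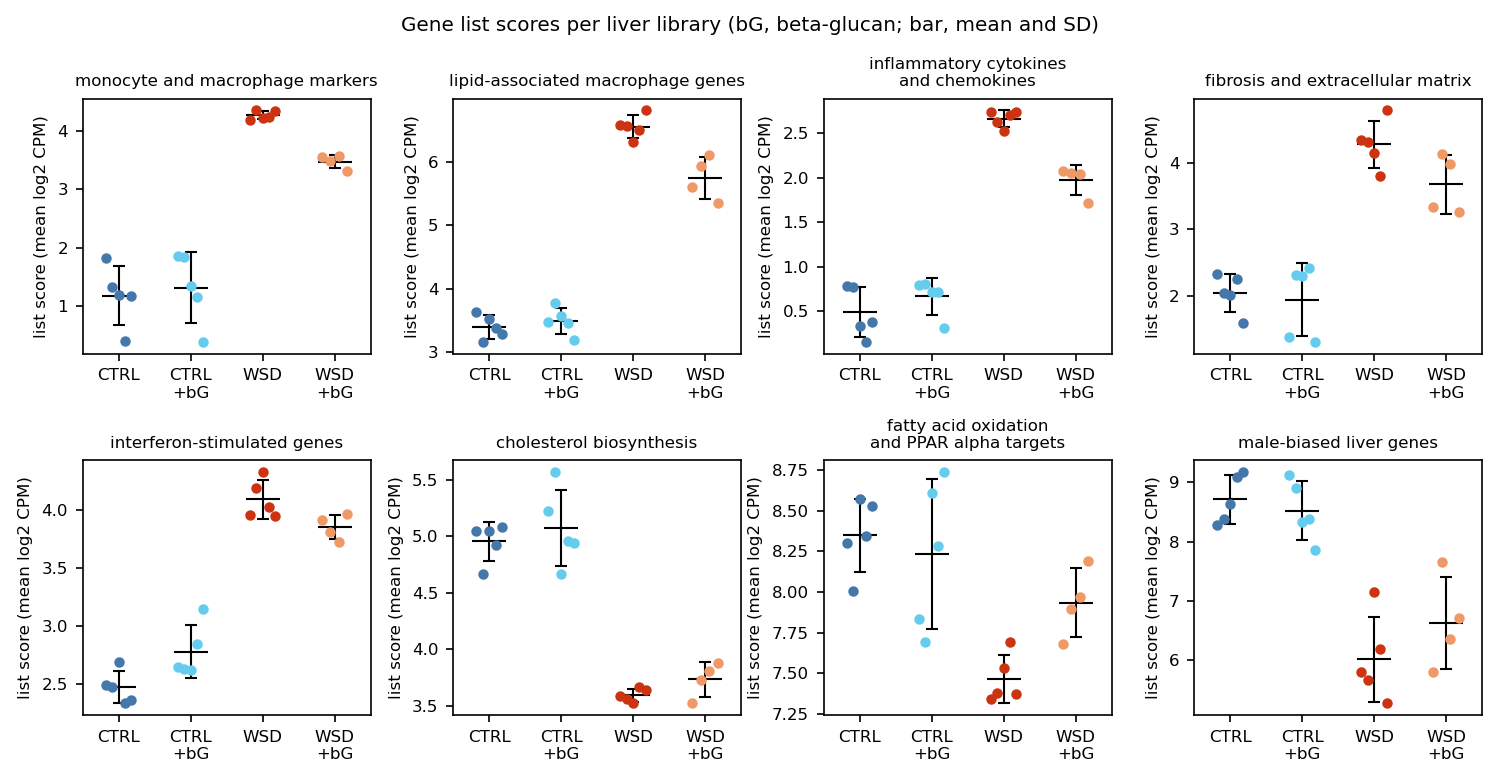
Scores of 8 gene lists (y axis, mean log2 CPM of the members) in each liver library (points) by group (x axis), with the group mean and SD as bars; each panel has its own y scale. WSD+beta-Glucan libraries lie between the CTRL and WSD means in the monocyte and macrophage panel, at 3.48 ± 0.12 against 4.27 ± 0.07 in WSD and 1.18 ± 0.51 in CTRL.

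Whether beta-glucan altered the liver of mice on WSD was the question of the comparison of WSD+beta-Glucan with WSD, which is the one the series title points to. With beta-glucan 6 of 19 lipid-associated macrophage genes were lower, and 12 genes, among them Prlr, were higher. Mmp12 (ENSMUSG00000049723) fell from 42.9 ± 7.62 CPM in WSD (SD, n = 5) to 14.6 ± 3.46 CPM in WSD+beta-Glucan (SD, n = 4), a log2 fold change of -1.56 ± 0.17 (SE, adjusted p = 0.00028). Lpl (ENSMUSG00000015568) fell from 178 ± 14.1 to 75.9 ± 16.8 CPM (-1.23 ± 0.16, adjusted p = 0.00238), and Trem2 fell to 9.37 ± 4.24 CPM (-1.46 ± 0.28, adjusted p = 0.0276). Prlr (ENSMUSG00000005268), the prolactin receptor, rose from 22.0 ± 5.48 to 48.6 ± 15.5 CPM (1.14 ± 0.24, adjusted p = 0.0476), a call lost in 18 of the 29 other settings (adjusted p from 0.0508 to 0.232). edgeR called 12 genes higher and 41 lower of 13594 tested, and 2118 genes had an unadjusted p under 0.05.

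The other genes at the high end were Pmm1, a phosphomannomutase (0.77 ± 0.14), Nr1i3, the xenobiotic receptor CAR (0.68 ± 0.13), Gabbr2 (0.64 ± 0.13), Tm7sf2 (0.63 ± 0.12) and Cyp2c38, a cytochrome P450 (0.62 ± 0.12). At the low end, besides Mmp12 and Trem2, were Mmp13, a collagenase (-1.60 ± 0.33), Gpnmb (-1.53 ± 0.32), Adam8, a metalloprotease of leukocytes (-1.49 ± 0.29), and Egr2, an immediate early transcription factor (-1.46 ± 0.30). Their adjusted p-values from edgeR lay between 0.0261 and 0.0475. Slc10a1 (0.65 ± 0.14, adjusted p = 0.0475) and Tm6sf2, which acts in lipoprotein secretion (0.52 ± 0.10, adjusted p = 0.0261), were also higher. The call of Gpnmb was lost in 20 of the 29 other settings (adjusted p from 0.0523 to 0.175), among them DESeq2 (adjusted p = 0.0721) and edgeR on these 9 libraries alone (adjusted p = 0.0641), and that of Slc10a1 in 19 (adjusted p from 0.0510 to 0.260).

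Lipid-associated macrophage genes had 6 members lower and 0 higher of 19 (12 and 0 adjusted over the list alone), with a median log2 fold change of -0.77 and camera adjusted p = 9.5e-17, or adjusted p = 0.00716 with an estimated correlation. Capg was among them (-1.05 ± 0.18, adjusted p = 0.0214). Inflammatory cytokines and chemokines had 1 lower and 0 higher of 29 (19 lower and 1 higher adjusted over the list alone, median -0.77, adjusted p = 0.00716 with an estimated correlation). The 1 gene was Ccl2, at 2.30 ± 0.589 CPM against 6.21 ± 0.998 in WSD (-1.43 ± 0.27, adjusted p = 0.0261), and Tnf did not pass (-1.08 ± 0.30, adjusted p = 0.102). Microbial sensing genes had 1 lower of 35 (11 adjusted over the list alone, median -0.50, adjusted p = 0.00779 with an estimated correlation). This was Unc93b1, which carries nucleic acid-sensing Toll-like receptors to endosomes (-0.50 ± 0.08, adjusted p = 0.0214). Clec7a was at -0.99 ± 0.25 (adjusted p = 0.0775), Cd14 at -1.15 ± 0.31 (adjusted p = 0.0916) and Tlr4 at -0.58 ± 0.31 (adjusted p = 0.368), none of which passed. Clec7a passed with DESeq2 (adjusted p = 0.00683), limma-voom (adjusted p = 0.000352), the 9 libraries alone (adjusted p = 0.00197), a term for the 3 libraries numbered 37, 39 and 40 (adjusted p = 0.0445) and 4 fits that left out 1 library (adjusted p from 0.0312 to 0.0489). Cd14 passed with DESeq2 (adjusted p = 0.0155), limma-voom (adjusted p = 0.0244) and without CTRL+beta-Glucan replicate 5 (adjusted p = 0.0485), and Tnf with limma-voom (adjusted p = 0.0207).

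Monocyte and macrophage markers had 0 members past the threshold over all genes and 19 of 24 lower adjusted over the list alone (median -0.80, camera adjusted p = 1.2e-17). The call was lost, with adjusted p = 0.130 with an estimated correlation. Ccr2 was at -0.88 ± 0.20 (adjusted p = 0.0634) and Adgre1, the macrophage antigen F4/80, at -0.60 ± 0.28 (adjusted p = 0.309). Genes of MHC class II presentation had 0 past the threshold and 7 of 10 lower adjusted over the list alone (median -0.80, adjusted p = 0.190 with an estimated correlation). Interferon-stimulated genes had 0 and 5 of 38 (median -0.21, adjusted p = 0.228 with an estimated correlation), where the 5 are those lower adjusted over the list alone. Fibrosis and extracellular matrix genes had 1 lower of 42, Mmp13, and 6 lower adjusted over the list alone (median -0.58, camera adjusted p = 7.4e-12), with adjusted p = 0.212 with an estimated correlation. Col1a1 was at 47.5 ± 26.8 CPM against 108 ± 43.8 in WSD (-1.18 ± 0.40, adjusted p = 0.181), and Timp1 at -1.47 ± 0.40 (adjusted p = 0.101). Col1a1 passed with limma-voom (adjusted p = 0.0253), Timp1 with DESeq2 (adjusted p = 0.0137) and limma-voom (adjusted p = 0.0144), and Ccr2 with both (adjusted p = 0.00257 and 0.00184), with the 9 libraries alone (adjusted p = 0.0165), with the term for the 3 libraries (adjusted p = 0.0195) and in 3 fits that left out 1 library (adjusted p from 0.0310 to 0.0489). Cell cycle genes had 0 past the threshold on either count (median -0.54, adjusted p = 0.0846 with an estimated correlation).

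On the hepatocyte side, fatty acid oxidation genes had 0 past the threshold over all genes and 25 of 42 higher adjusted over the list alone (median 0.37, camera adjusted p = 2.7e-16). This call was lost, with adjusted p = 0.199 with an estimated correlation. General hepatocyte markers had 0 past the threshold and 2 of 20 higher adjusted over the list alone (median 0.22, adjusted p = 0.293 with an estimated correlation). Mitochondrial transcripts had 0 of 13 on either count (median 0.42, adjusted p = 0.320 with an estimated correlation), and pericentral genes 0 past the threshold and 4 higher and 1 lower of 18 adjusted over the list alone (median 0.30, adjusted p = 0.173 with an estimated correlation). The mean scores of these 4 lists differed by 0.47, 0.25, 0.34 and 0.39, and none passed the exact permutation test (adjusted p = 0.106, 0.141, 0.195 and 0.127). Cpt1a was at 562 ± 116 CPM against 400 ± 63.8 in WSD (0.49 ± 0.19, adjusted p = 0.213). Xenobiotic metabolism genes had 2 higher of 40, Nr1i3 and Cyp2c38, and 10 higher adjusted over the list alone (median 0.25, adjusted p = 0.263 with an estimated correlation). Cholesterol biosynthesis had 1 higher of 27, Tm7sf2, on both counts (median 0.22, adjusted p = 0.371 with an estimated correlation). De novo lipogenesis had 0 past the threshold on either count (median 0.09, camera adjusted p = 0.643), with Fasn at -0.36 ± 0.19 (adjusted p = 0.368) and Scd1 at 0.18 ± 0.23 (adjusted p = 0.733). Male-biased genes had 0 on either count (median 0.54, adjusted p = 0.398 with an estimated correlation).

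As a test with the library as the unit, the mean log2 CPM of each list was compared between the groups by exact permutation. For WSD+beta-Glucan against WSD the smallest p was 0.0159, the smallest possible, and after adjustment over 40 lists the smallest was 0.0705, so 0 lists passed. The score differences at this smallest p were not only those of immune lists: they included 0.90 for mesothelial markers, 0.30 for adipocyte markers and -0.64 for immediate early genes. For WSD against CTRL 30 of 40 lists passed in the same exact test. The number of genes called for WSD+beta-Glucan depended on the tool and on single libraries: DESeq2 called 436, limma-voom 692, and edgeR on these 9 libraries alone 457. It was 47 without the 3 libraries numbered 37, 39 and 40 (26 of them among the 53), 258 with a model term for those 3, and 2 without WSD+beta-Glucan replicate 1, 2 or 4 or WSD replicate 5. It was 3 without WSD replicate 1 or 2, 33 without WSD replicate 3, 85 without CTRL+beta-Glucan replicate 1, 97 without CTRL replicate 1 and 184 without CTRL+beta-Glucan replicate 5. None of the calls was higher without WSD+beta-Glucan replicate 1, 2 or 4 or WSD replicate 1, 2 or 5. There were 31 higher and 44 lower without WSD replicate 4, 22 and 52 without WSD+beta-Glucan replicate 3, and 46 and 411 with the 9 libraries alone. Mmp12 and Lpl passed in each of the 29 other settings, and each of the other 16 genes named as past the threshold lost its call in at least 6 of them.

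**Figure D3:**
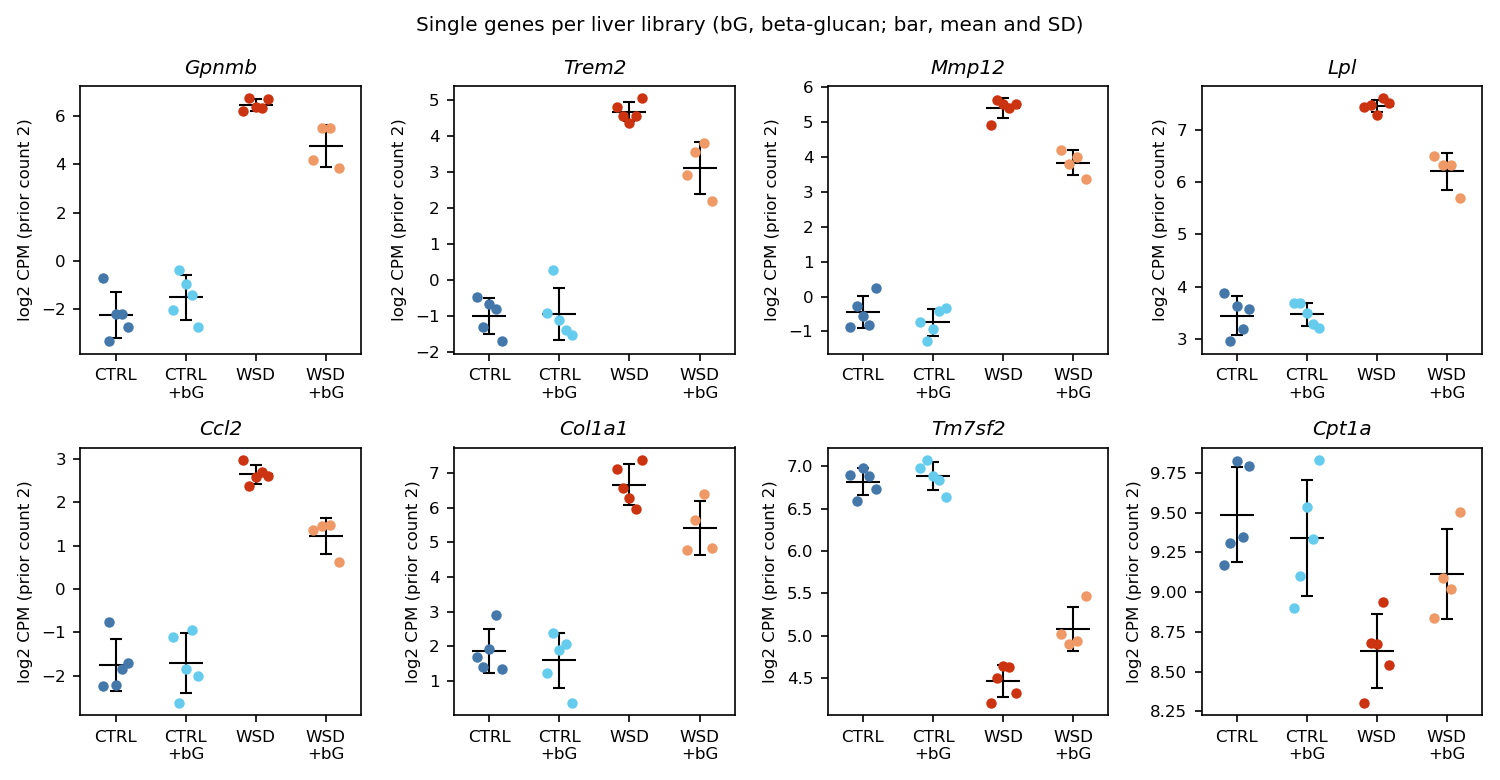
Log2 CPM (y axis, prior count 2) of 8 genes in each liver library (points) by group (x axis), with the group mean and SD as bars; each panel has its own y scale. Mmp12, Lpl, Trem2, Gpnmb and Ccl2 are lower and Tm7sf2 is higher in WSD+beta-Glucan than in WSD, while Col1a1 and Cpt1a did not pass the test of that difference (adjusted p = 0.181 and 0.213).

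What beta-glucan did on the control treatment was the question of CTRL+beta-Glucan against CTRL. Epha2 (ENSMUSG00000006445), an ephrin receptor kinase, was the 1 gene that passed: it rose from 31.3 ± 5.7 CPM in CTRL (SD, n = 5) to 57.9 ± 12.3 CPM in CTRL+beta-Glucan (SD, n = 5), a log2 fold change of 0.89 ± 0.13 (SE, adjusted p = 0.0284). edgeR called 0 genes lower, 775 genes had an unadjusted p under 0.05, DESeq2 called 6 genes, and limma-voom called 2, of which Epha2 was not one. None of the 24 genes fixed beforehand passed. Srebf1 was at 0.72 ± 0.17 (adjusted p = 0.554), Fasn at 0.31 ± 0.18 (adjusted p = 0.855), Clec7a at 0.32 ± 0.35 (adjusted p = 0.894) and Cyp7a1 at -0.66 ± 0.76 (adjusted p = 0.894). In simulated data of this comparison with known changes, edgeR recovered 55.9% of 34 genes raised 1.5-fold. It recovered 80.6% of the genes changed 2-fold in either direction and 97.0% of those changed 4-fold. Each gene was simulated independently of the others, so these shares leave out genes that move together between livers.

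By camera with the preset correlation 13 lists passed in this comparison, and none did with an estimated correlation, where the lowest adjusted p was 0.364. Interferon-stimulated genes had a median of 0.35 (camera adjusted p = 7.2e-13, adjusted p = 0.364 with an estimated correlation), with 0 of 38 past the threshold and 1 adjusted over the list alone. Immediate early genes had a median of 0.43 with 0 of 18 past the threshold and 1 adjusted over the list alone (adjusted p = 0.439 with an estimated correlation). Genes of endoplasmic reticulum stress had a median of -0.21 and erythroid markers one of -0.60, both with 0 members past the threshold on either count (adjusted p = 0.600 for both with an estimated correlation). The acute phase list had a median of -0.17 (adjusted p = 0.968 with an estimated correlation); within the beta-glucan groups its members were higher by a median of 0.97 in the 3 libraries numbered 37, 39 and 40, of which 2 are in CTRL+beta-Glucan. Fatty acid oxidation genes had a median of -0.07 (camera adjusted p = 0.0249, adjusted p = 0.968 with an estimated correlation), and their camera direction turned to up without those 3 libraries (adjusted p = 0.000182) and without CTRL+beta-Glucan replicate 2 (adjusted p = 0.909). Epha2 lost its call without WSD+beta-Glucan replicate 2, CTRL+beta-Glucan replicate 3, 4 or 5, WSD replicate 2, 3, 4 or 5, or CTRL replicate 1, 2, 4 or 5 (adjusted p from 0.0502 to 0.148), in edgeR on these 10 libraries alone (adjusted p = 0.350) and with limma-voom (0.80, adjusted p = 0.125); 2 genes were called without CTRL+beta-Glucan replicate 2.

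The effect of WSD in mice given beta-glucan was measured by WSD+beta-Glucan against CTRL+beta-Glucan, which shares no library with WSD against CTRL. Gpnmb was again among the highest, at 30.6 ± 16.9 CPM (SD, n = 4) against 0.315 ± 0.249 CPM (SD, n = 5), a log2 fold change of 6.61 ± 0.50 (SE, adjusted p = 9.29e-08). Adipose-type genes stood beside it: Cfd, the adipokine adipsin, changed by 6.26 ± 0.69 (adjusted p = 7.32e-06) and Cidea, a lipid droplet protein, by 6.02 ± 0.55 (adjusted p = 8.71e-07). Sterol synthesis genes were among the lowest, with Fdft1, the squalene synthase, at -4.14 ± 0.66 (adjusted p = 0.000176) and Sqle, the squalene epoxidase, at -3.56 ± 0.51 (adjusted p = 6.2e-05). edgeR called 2593 genes higher and 2063 lower, with 6074 at an unadjusted p under 0.05.

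The remaining genes at the high end were Sdcbp2 (6.03 ± 0.69), Ephb2 (5.52 ± 0.43) and Cyp2b9, a female-biased cytochrome P450 (5.43 ± 0.82). Sdcbp2 had only 9 reads over the 5 CTRL+beta-Glucan libraries, so the size of its fold is uncertain. Those at the low end were Serpina1e (-4.15 ± 0.66), Hsd3b5, a male-biased steroid dehydrogenase (-4.14 ± 0.92), Adgrf1 (-3.77 ± 0.54) and Cyp2c69 (-3.59 ± 0.52). Monocyte and macrophage markers rose in 23 of 24 cases (24 adjusted over the list alone, median 2.17, adjusted p = 0.0259 with an estimated correlation), and lipid-associated macrophage genes in 15 of 19 (15 adjusted over the list alone, median 2.17, adjusted p = 0.00264 with an estimated correlation). Interferon-stimulated genes rose in 29 of 38 cases (29 adjusted over the list alone, median 0.97, adjusted p = 0.0259 with an estimated correlation). Cholesterol biosynthesis genes fell in 24 of 27 (24 adjusted over the list alone, median -1.17, adjusted p = 0.0259 with an estimated correlation). Fibrosis genes rose in 37 of 42 cases and fell in 1 (37 and 1 adjusted over the list alone, median 1.70, adjusted p = 0.127 with an estimated correlation). Cholangiocyte markers rose in 13 and fell in 1 of 17 cases (15 and 1 adjusted over the list alone, median 2.30, adjusted p = 0.624 with an estimated correlation), and the gene that fell was Sox9, a call lost without the 3 libraries numbered 37, 39 and 40 (-0.66, adjusted p = 0.104). Adipocyte markers rose in 4 of 6 cases (4 adjusted over the list alone, median 2.67, adjusted p = 0.0259 with an estimated correlation). Beside them the mean score of the mesothelial markers was higher by 1.72 (exact permutation, adjusted p = 0.0265), with 1 of 6 markers past the threshold and 4 adjusted over the list alone (camera adjusted p = 0.0621). Male-biased genes fell in 16 of 26 (18 adjusted over the list alone, median -1.45, adjusted p = 0.257 with an estimated correlation).

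Between the comparisons of WSD with CTRL and of WSD+beta-Glucan with CTRL+beta-Glucan the log2 fold changes had a Pearson r of 0.845 across 13594 genes, which are not independent replicates (SE 0.1 from leaving out libraries in turn). Both comparisons called 2276 genes higher, against 673 for independent lists of these sizes, and 1687 lower, against 558.5. Opposite calls were made for 2 genes. Without the filter on low counts r was 0.432.

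The test of the difference between the beta-glucan effects on the 2 backgrounds, which is also the difference between the WSD effects, called 1 gene. This was Unc93b1 (ENSMUSG00000036908), at 68.7 ± 3.96 CPM in WSD (SD, n = 5), 48.7 ± 4.64 in WSD+beta-Glucan (n = 4), 29.2 ± 2.95 in CTRL (n = 5) and 35.0 ± 2.32 in CTRL+beta-Glucan (n = 5), a difference of -0.76 ± 0.12 in log2 (SE, adjusted p = 0.0366). edgeR called 0 genes in the other direction, 1865 genes had an unadjusted p under 0.05, and DESeq2 called 139 genes and limma-voom 1. Srebf1, 1 of the 24 genes fixed beforehand, did not pass in the main fit but passed in 1 of the 28 other settings. Lipid-associated macrophage genes had a median difference of -0.86 and inflammatory cytokines and chemokines one of -0.97. For both lists 0 members passed over all genes, 7 and 15 were lower adjusted over the list alone, and camera gave adjusted p = 1.6e-10 and 6.2e-11, or adjusted p = 0.0502 for both with an estimated correlation. Interferon-stimulated genes had a median difference of -0.54, with 0 of 38 past the threshold and 16 lower adjusted over the list alone (adjusted p = 0.0848 with an estimated correlation). Of the 19 fits that left out 1 library, Unc93b1 passed only in those without WSD+beta-Glucan replicate 3, CTRL+beta-Glucan replicate 5, WSD replicate 4 and CTRL replicate 3; in the others its adjusted p reached 0.171, and it was 0.104 without the 3 libraries numbered 37, 39 and 40. Without CTRL+beta-Glucan replicate 5, 81 genes were called.

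How far beta-glucan opposed the change made by WSD was measured over the genes called in WSD against CTRL. Because the WSD libraries enter both comparisons, they were split in all 10 ways, 3 for the calls and the other 2 for the beta-glucan effect. On average over the splits 80.9% of the called genes moved in the opposite direction with beta-glucan (from 77.2% to 84.0%), against 85.8% with all WSD libraries in both. The SE of this share from leaving out libraries in turn was 6 percentage points. In 20 simulated data sets in which WSD+beta-Glucan was given the WSD means, unsplit, the share was 56.1% (from 55.1% to 57.3%). Each gene was simulated independently of the others, so this range leaves out genes that move together between livers. The slope of the opposing change on the change made by WSD was 0.212 on average (from 0.134 to 0.282). The covariance of the log2 fold changes was -0.2741 observed and -0.0427 simulated, a difference of -0.2314.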

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

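All tests of explanations in this part were chosen after the results were seen, except the test of the circadian clock genes in the 3 libraries numbered 37, 39 and 40, which was planned.

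The smaller response to WSD in livers given beta-glucan was weighed first: 80.9% of the genes called in WSD against CTRL moved in the opposite direction with beta-glucan. The use of the same WSD libraries in both contrasts is argued against, since the lowest share with these libraries split was 77.2%. The highest simulated share was 57.3%, but genes were simulated independently of each other. A chance difference between livers that moves many genes together was therefore not tested. Different sequencing sheets are argued against as the whole cause, since the share was 79.5% without the 3 libraries numbered 37, 39 and 40. The other WSD+beta-Glucan libraries carry the S numbers 18 to 20, the highest in the series. An effect of sample order thus cannot be told apart from that of the group. A lower share of all cells other than hepatocytes cannot be told apart and may contribute, since all 8 other scores (differences from -0.46 to -0.04) were lower and the hepatocyte score was higher (0.25), none past the threshold. It would lower all markers alike, apart from genes with few counts, whose changes the prior count of 2 shrinks. The macrophage score minus the mean of 8 other scores (endothelial, stellate, cholangiocyte, Kupffer, dendritic, neutrophil, T and NK, B and plasma cell) fell by 0.57, from 2.06 ± 0.18 in WSD (n = 5) to 1.5 ± 0.07 in WSD+beta-Glucan (n = 4, exact permutation p = 0.0159). Against each score alone the difference lay between -0.76 and -0.33, with exact permutation p under 0.05 for 5 of 8. The macrophage score had the largest fall of these scores (-0.79) and was picked after the values were seen. A negative difference was thus favoured by the choice, and the comparison cannot decide. An effect of beta-glucan, which may include fewer or less activated macrophages, stays open as a hypothesis, as do differences in weight, food intake or disease stage, which the labels do not give.

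The 3 libraries numbered 37, 39 and 40 were weighed next: a model term for them called 143 genes as higher and 90 as lower in them. A batch is a candidate explanation, as is anything else that these 3 libraries share: of the 40 choices of 1 WSD+beta-Glucan and 2 CTRL+beta-Glucan libraries only 1, the real one, called as many genes (233), and the highest other choice called 1. Lower depth is argued against, since their gap on the second principal component was 40.6 as sequenced and 40.4 after all libraries were thinned to the same total. Another time of day at collection cannot be told apart: 0 of 19 circadian clock genes passed the threshold, but their mixed fry p was 0.01328. The mixed fry test of limma counts changes in either direction, and its p was not adjusted. Its p was not particular to clock genes: it was 1.1e-09 for bile acid genes and 3.3e-07 for acute phase genes. Camera with the preset correlation gave the clock list adjusted p = 0.4965. The acute phase scores of the 3 libraries (8.25 to 8.87) lay within the range of CTRL (7.29 to 8.94) and above the other 6 beta-glucan libraries (6.81 to 7.97); whether the 3 or the 6 stand apart in these genes was not separated from a batch, and apart from the time of day no biological explanation was tested.

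The difference between both beta-glucan effects was tested directly. Unc93b1 passed with a difference of -0.76. By camera with the preset correlation 24 lists differed; none did with an estimated correlation, where the lowest adjusted p was 0.0502. Immune lists had lower values with beta-glucan on WSD relative to the control treatment: the median difference was -1.20 for MHC class II presentation, -0.97 for inflammatory cytokines and chemokines, -0.92 for monocyte and macrophage markers, -0.86 for lipid-associated macrophage genes, -0.69 for T and NK cell markers, -0.54 for interferon-stimulated genes, and -0.49 for both dendritic cell markers and microbial sensing. It was -0.73 for fibrosis and extracellular matrix, -0.53 for hepatic stellate cell markers, -0.45 for endothelial markers, -1.07 for immediate early genes, -0.60 for senescence, death and damage, and -0.24 for cell cycle genes. Positive median differences were found for erythroid markers (0.98), male-biased liver genes (0.62), fatty acid oxidation (0.45), pericentral genes (0.43), mitochondrial transcripts (0.39), lipid droplet genes (0.25), xenobiotic metabolism (0.23), glucose metabolism (0.20), bile acid genes (0.18) and hepatocyte markers (0.18).

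A library far from the others of its group was looked for with Dixon's ratio, the gap to the nearest library over the range of the group, against Dixon's 95% critical value. The ratio was exceeded in 35 of 524 groups of values, where chance gives about 1 in 20 groups, or 26.2. The 35 include ratios of 1.0 for Timp1, Egr2, Mmp13 and Sprr1a in CTRL. These were fixed by the lack of reads in all other CTRL libraries, whatever the count in the remaining one. No library exceeded it more than 4 times, which CTRL replicates 3 and 4 and WSD+beta-Glucan replicate 4 did. In WSD+beta-Glucan, replicate 1 was highest for acute phase genes (ratio 0.95), with a score of 8.67 against 7.94 to 7.97 in the others. In the same group replicate 4 was lowest for inflammatory genes (0.89), Ccr2 (0.96) and Ccl2 (0.87) and highest for adipocyte markers (0.90). Replicate 2 was lowest for de novo lipogenesis (0.96) and Tnf (0.85) and highest for mesothelial markers (0.97), and replicate 3 was lowest for endothelial markers (0.86) and erythroid markers (0.84). In WSD, replicate 5 was lowest on the second principal component (0.76) and for Elovl3 (0.73), and replicate 3 highest for Saa4 (0.72).

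In CTRL, replicate 1 was highest for B and plasma cell markers (0.80) and lowest for pericentral genes (0.76), and it alone had reads of Timp1 (1.0). Replicate 2 was lowest for G6pc (0.79) and Nfil3 (0.77) and alone had a read of Egr2 (1.0). Replicate 3 was highest for lipid droplet genes (0.78), Fgf21 (0.87) and Gabbr2 (0.78) and alone had reads of Mmp13 (1.0). Replicate 4 was lowest for periportal genes (0.75), Adgre1 (0.77) and Mpeg1 (0.73) and alone had a read of Sprr1a (1.0). In replicate 5 the 50 most abundant genes took 42.5% of the counts, against 39.6% to 40.1% in the other CTRL libraries (0.83). In CTRL+beta-Glucan, replicate 3 was highest for adipocyte markers (0.78), Cfd (0.72) and Pmm1 (0.77), replicate 2 for Tm6sf2 (0.78) and replicate 4 for Scd1 (0.78). Replicate 5 was lowest for inflammatory genes (0.82) and Mup15 (0.74).

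The reads of the 569 transcripts left out of all comparisons, because the annotation lacks them, were more frequent in WSD, with a mean of 0.101% of the reads, than in CTRL, with 0.0697 ± 0.00526% (SD, exact permutation p = 0.00794, n = 5 each). They took 0.0927% in WSD+beta-Glucan (n = 4) and 0.0722% in CTRL+beta-Glucan (n = 5, exact permutation p = 0.0159). Which genes they stand for was not resolved.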

How the results depend on the processing

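The alternatives for the gene lists, other than the estimated correlation, the adjustment over the list alone and the camera test without the 3 libraries numbered 37, 39 and 40, were chosen after seeing the data; all others were planned. The number of genes past the threshold in WSD against CTRL (7208) stayed between 6448 and 7650 over all alternatives, and that of WSD+beta-Glucan against CTRL+beta-Glucan (4656) between 3400 and 4990. The median log2 fold change of all genes in WSD against CTRL was -0.042 with TMM, -0.006 with RLE and -0.033 with TMM without the 50 most abundant genes.

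The count of 53 genes in WSD+beta-Glucan against WSD changed with the tool and with single libraries. It was 436 with DESeq2, 692 with limma-voom, 457 with only the 2 groups, 258 with a term for the 3 libraries and 35 with transcript length offsets. It stayed within 1.5-fold with RLE (51), no filter (36), the stricter filter (52), without the 3 libraries (47) and with TMM without the 50 most abundant genes (40). Leaving out 1 library gave between 2 genes (without WSD+beta-Glucan replicate 1, 2 or 4 or WSD replicate 5) and 184 (without CTRL+beta-Glucan replicate 5). The fit to only the 2 groups drops 10 libraries and estimates the spread from the other 9; the cause of the other changes was not tested. Of the 18 genes named as past the threshold there, 2 passed in all 29 alternatives (Mmp12 and Lpl), 154 of the 522 values missed the threshold and 0 changed direction. In WSD against CTRL 95 of 96 named genes passed in all, and the exception was Cidec. In WSD+beta-Glucan against CTRL+beta-Glucan 79 of 87 passed in all, and 13 of the 2517 values missed the threshold.

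For CTRL+beta-Glucan against CTRL, with 1 gene, DESeq2 gave 6, limma-voom 2, only the 2 groups 0, the data without the 3 libraries 5, the term for them 2, and leaving out 1 library 0 to 2. For the difference of the beta-glucan effects, with 1 gene, DESeq2 gave 139, the data without the 3 libraries 2, the term 2, and leaving out 1 library 0 to 81. The cause was not tested. The agreement of the WSD effects (r = 0.845) was 0.432 with no filter, where genes with few counts enter, 0.794 without the 3 libraries and 0.765 to 0.860 when 1 library was left out. The share of opposed genes (80.9%) ranged from 77.1% to 84.1% when 1 library was left out.

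Among lists that passed camera in the main setting or in the alternative, directions turned only in CTRL+beta-Glucan against CTRL. Turns of lists that passed in neither were not counted. Without the 3 libraries, 2 of which are in that contrast, they turned for monocyte and macrophage markers (adjusted p = 0.0127), neutrophil markers (0.0143), cholesterol biosynthesis (0.234), fatty acid oxidation (0.000182), lipid droplets (0.00546), xenobiotic metabolism (0.0127), NRF2 targets (0.0161) and hepatocyte markers (0.0488). With the term for them they turned for neutrophil markers (0.00925), fatty acid oxidation (0.0575) and xenobiotic metabolism (0.0179). For fatty acid oxidation the adjusted p ran from 1.35e-05 to 0.909 when 1 library was left out, and the direction turned without CTRL+beta-Glucan replicate 2. The estimated correlation ended 15 of the list calls in WSD against CTRL, 28 in WSD+beta-Glucan against WSD, 13 in CTRL+beta-Glucan against CTRL, 13 in WSD+beta-Glucan against CTRL+beta-Glucan and 24 in the difference, by allowing for the correlation between members.

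In simulated data of WSD+beta-Glucan against WSD, at the depth and group sizes of this series, edgeR recovered 52.9% of 34 genes raised 1.5-fold. It recovered 83.6% of the genes changed 2-fold in either direction and 98.5% of those changed 4-fold, and called 5 unchanged genes. DESeq2 called 25 unchanged genes there and limma-voom 4. Genes were simulated independently of each other here as well, so these values leave out genes that move together between livers.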

Other observations

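The genes singled out in the next paragraphs were chosen after their values were seen, as were all tests of explanations in this part.

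Members of the circadian clock list moved in both directions in WSD against CTRL, with 3 higher and 6 lower of 19 (3 and 6 adjusted over the list alone, median 0.04, camera adjusted p = 0.368). Dbp, an output gene of the clock, changed by 2.76 ± 0.52 (adjusted p = 0.000334), and Arntl, which encodes the activator BMAL1, by -1.14 ± 0.16 (adjusted p = 6.13e-06). Cry1, a repressor of the clock, changed by -1.11 ± 0.14 and Nfil3, a repressor of Dbp targets, by -1.44 ± 0.18. With beta-glucan in both groups the WSD effect was 2.48 ± 0.53 for Dbp, -0.99 ± 0.17 for Arntl, -1.18 ± 0.16 for Cry1 and -1.24 ± 0.19 for Nfil3. In WSD+beta-Glucan against WSD none of these 4 passed with edgeR (adjusted p from 0.607 to 0.928). The labels give no time of collection.

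Of the remaining lists in WSD against CTRL, adipocyte markers had 4 members higher and 1 lower of 6 (4 and 1 adjusted over the list alone, median 3.17, camera adjusted p = 0.0574), and their mean score was higher by 2.45 (exact permutation, adjusted p = 0.0127). Cfd changed by 4.44 ± 0.61 and Cidea by 4.42 ± 0.48; Cidea also belongs to the lipid droplet list. The acute phase list had 4 higher and 9 lower of 27 (4 and 9 adjusted over the list alone, median -0.38, camera adjusted p = 0.649), with Steap4, a metalloreductase, at 2.46 ± 0.23 and Hamp, the iron hormone hepcidin, at -1.61 ± 0.36. Pericentral genes had 4 higher and 8 lower of 18 (4 and 8 adjusted over the list alone, median -0.24, camera adjusted p = 0.420). Xenobiotic metabolism had 10 higher and 19 lower of 40 (11 and 19 adjusted over the list alone), with a median of -0.35, a mean of 0.14 and camera direction down (adjusted p = 0.192). Endoplasmic reticulum stress had 5 higher and 5 lower of 29 (5 and 3 adjusted over the list alone), with a median of -0.24, a mean of 0.05 and camera adjusted p = 0.547. Among the receptors for short-chain fatty acids and bile acids 1 rose and 1 fell of 3 (1 and 1 adjusted over the list alone, camera adjusted p = 0.507; mean score higher by 0.97, exact permutation, adjusted p = 0.0127), and the gene that rose was Hcar2, the butyrate and niacin receptor (3.70 ± 0.46). Erythroid markers had 3 lower of 8, mesothelial markers 1 higher of 6, and gallbladder and intestinal markers 1 higher and 1 lower of 4, with the same counts adjusted over the list alone (camera adjusted p = 0.113, 0.609 and 0.851).

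Within WSD+beta-Glucan and CTRL+beta-Glucan, the 3 libraries numbered 37, 39 and 40 had higher acute phase genes, with 10 of 27 past the threshold, a median log2 fold change of 0.97 and camera adjusted p = 0.0275 with an estimated correlation. Saa4, a serum amyloid, was higher by 1.23 ± 0.14 (adjusted p = 0.000277), Fgb, a fibrinogen chain, by 0.71 ± 0.10 (adjusted p = 0.00248) and Cxcl1, a neutrophil attractant, by 2.21 ± 0.31. The acute phase scores of these 3 libraries (8.25 to 8.87) lay within the range of CTRL (7.29 to 8.94) and around that of WSD (8.28 to 8.49), while the other 6 beta-glucan libraries were at 6.81 to 7.97. Neutrophil markers had 1 of 9 higher, a median of 1.55 and camera adjusted p = 0.0275 with an estimated correlation. Fatty acid oxidation genes had 7 lower and 0 higher of 42, with a median of -0.47. Their camera adjusted p was 1.2e-17 with the preset correlation and 0.408 with an estimated one. The largest increases among the genes called were those of the immunoglobulin genes Ighg1 (5.16 ± 1.13) and Ighg2c (4.62 ± 0.86).

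The lower male-biased liver genes in WSD were weighed as a pattern: 22 of 26 members passed as lower. Reads shared between near-identical copies are argued against as the whole cause, since 7 of the 8 members outside the multigene families also passed as lower. A lower share of hepatocytes is argued against as the whole cause, since the male-biased score minus the hepatocyte score fell by 1.99, from -3.26 ± 0.50 in CTRL to -5.26 ± 0.60 in WSD (exact permutation p = 0.00794, n = 5 each). A shift toward the female pattern may contribute but cannot be told apart: of 16 female-biased genes 6 rose (Ntrk2, Cyp2b9, Cyp2b13, Cyp2a4, Spink1 and Atp6v0d2, the last also a lipid-associated macrophage gene) and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.38, a mean of 0.37 and camera adjusted p = 0.804. An effect of WSD on these genes stays open as a hypothesis.

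To see whether chance could give as many calls, the libraries of each contrast were regrouped into groups of the same sizes, 80 splits for each, the real one included. In WSD against CTRL chance is argued against, since only 1 of the 80 splits, the real one, called as many as 7208 genes. This is the smallest share that the test can give, and the highest other split called 343. For WSD+beta-Glucan against WSD chance is argued against, at a share of 2 of 80, but not excluded. Of 126 possible splits 80 were run, and 1 other split called 86 genes against the real 53. That split put WSD+beta-Glucan replicates 2 and 3 with WSD replicates 1 and 5. The real count was 2 without WSD+beta-Glucan replicate 1, 2 or 4 or WSD replicate 5, 3 without WSD replicate 1 or 2, 33 without WSD replicate 3, and 85, 97 and 184 without CTRL+beta-Glucan replicate 1, CTRL replicate 1 and CTRL+beta-Glucan replicate 5. In WSD+beta-Glucan against CTRL+beta-Glucan chance is argued against, since 1 of 80 splits, the real one, called 4656 genes. The highest other, with 2597, put only CTRL+beta-Glucan replicate 3 with the WSD+beta-Glucan libraries. In both WSD contrasts too, only 80 of 126 possible splits were run. For CTRL+beta-Glucan against CTRL chance cannot be excluded, since 13 of 80 splits called at least the real 1 gene. The highest called 1056 genes, with CTRL+beta-Glucan replicates 1, 2 and 3 and CTRL replicates 1 and 2 against the other 5 libraries, which points to a structure of the samples that the groups do not follow. Both CTRL+beta-Glucan libraries numbered 39 and 40 are on 1 side of that split, and 5 genes were called in this contrast without the 3 libraries numbered 37, 39 and 40. For the difference of the effects chance cannot be excluded either, with 7 of 80 splits as large as the real 1 gene and a highest other of 1022, which also points to such a structure.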
